A study of Macaca mulatta with 7 samples.

How the data were processed

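ChIP-seq had been done on frozen term placenta of the rhesus monkey with antibodies against H3K27ac, H3K4me1 and H3K4me3. Per the labels' protocols, chromatin came from 2 placentas, was sheared by sonication, and libraries were sequenced as single-end reads of 50 bp. There were 2 libraries for each mark and 1 input library. Samples were grouped by the antibody in their labels. Replicate numbers came from the titles, and which library came from which placenta is not given in the sources used here.

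The authors deposited 3 peak lists in BED format. Per the labels, the list of a mark belonged to both libraries of that mark; how the libraries were combined is not given in the sources used here. Per the submitters' processing notes, the tools were Trim Galore 0.6.4, Bowtie2 2.3.5, SAMtools 1.10 and MACS2 2.2.5, and the genome build was Mmul_10. Parameters, any use of the input library as control, and filters are not given in the sources used here. The deposited lists give a whole-number score per peak, whose formula is not given in the sources used here. The score was used to rank or filter peaks within a list and, by rank, to correlate overlapping peaks of different lists. In 1 alternative it was multiplied by peak width to rank clusters, which rests on a scale that is not known. The lowest score was 10 for H3K4me1 and 20 for the other marks, and the smallest gap between neighbouring peaks was 177 bp for H3K4me1 and 47 bp for the others, so the lists differed in lower limit and spacing, and their lengths cannot be compared as amounts of modification. Within each list the peak names were numbered without gaps. Peaks removed from the end of a list, or before a renumbering, would leave no trace in these names. Peaks did not overlap within a list. No read counts or coverage were used, so depth is unknown and no counting error can be given. Short calls can split 1 broad domain of a histone mark into several peaks, which raises counts and lowers widths.

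All calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Peaks were called overlapping when they shared at least 1 base. The overlap of unrelated lists was estimated by rotating a list along each chromosome by its own random distance, 1000 times, which keeps widths and spacing. The test was a two-sided permutation test on these rotations. Shares, differences of shares and densities carry 95% percentile intervals from 1000 bootstrap draws of 5-Mb blocks; for correlations over bins 200 draws were used. Alternatives to the main overlap rule, wide domains and the strongest 1% of peaks were set against 200 rotations, the local shift against 1000 draws. Peaks are not biological replicates, so tests and intervals describe these lists. Chromosome spans were taken as the highest peak end in any list, 2851.2 Mb in all. Candidate distal regions, clusters of H3K27ac (gaps of up to 10 kb) and H3K4me3 domains (gaps of up to 1 kb) were built as described with their results. On simulated lists of 20000 peaks with 0%, 10% and 30% of peaks placed on H3K4me1 peaks, the excess over rotation was 0.0022, 9.88 and 29.2 percentage points. On 200 simulated lists the block bootstrap interval held the planted share in 188. The blocks of these lists were independent and held the same number of peaks each, so the result does not extend to unequal or dependent blocks.

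The peak counts, overlaps, combinations, candidate distal regions, clusters and wide domains, their alternatives and the regions to be named were fixed before the data were examined, except those said to be chosen later. Not in that plan were the comparisons by score, around peak centres, between overlapping pairs, and between chromosomes or bins. The random placement of H3K27ac peaks and the comparisons of other marks in wide domains and top clusters were not in it either. The rule for naming was the 10 widest H3K4me3 domains, the 10 top clusters of H3K27ac and the 5 candidate distal regions with the highest score; for each it also asked for the nearest gene, along with a set of fixed genes and 16 fixed gene lists. No genome sequence or gene annotation of Mmul_10 was used. The gene table at hand was of another assembly, T2T-MMU8v2.0, and coordinates were not moved between builds. Peaks at transcription start sites, the gene lists and named genes, repeat content and sequence motifs were therefore not analysed here. For the same reason, the distal criterion used H3K4me3 peaks in place of annotated start sites, wide domains were taken from all H3K4me3 domains, and the planned test of the top clusters against gene lists was not analysed here. The alternatives tried were the stronger 50% of each list by score, an overlap of at least 50% of the peak or reciprocally, other distances for distal regions, other joining distances, and other rankings. Those added after seeing the data were a local shift of 20 to 200 kb in place of rotation, a common lowest score of 20, the absence of a shared base with H3K4me3 in place of the 2-kb distance, lists shortened to the length of the shortest, a weighting of peaks outside the top clusters to the same score deciles, and leaving out the 10 bins with the most H3K4me3 peaks that met no other mark.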

Results

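Histone modifications that mark regulatory DNA were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in term placenta of the rhesus monkey (Macaca mulatta). H3K4me3 is enriched at promoters, H3K4me1 at enhancers and around promoters, and H3K27ac at promoters and enhancers that are active. The series held 7 libraries, with 2 for each of the 3 antibodies and 1 input library without antibody. The values available were 3 peak lists, 1 per mark, and the labels of both libraries of a mark pointed to the same list. No value could therefore be compared between replicates. Unless stated otherwise, the intervals given below are 95% block bootstrap intervals over 5-Mb segments of the genome, and they describe variation along the genome and not between animals. Read totals of the libraries are not given in the sources used here, so the depth behind each list is unknown. All positions refer to the build Mmul_10 and are 1-based.

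The first question was how many peaks each list held and how much of the genome they covered, which is not a measure of the amount of a modification. The H3K4me1 list was the longest, with 99276 peaks (93770 to 104902) that covered 35.7 Mb. The H3K4me3 list held 57544 peaks (54016 to 61171) over 15.7 Mb, and the H3K27ac list held 53712 peaks (50117 to 57296) over 14.1 Mb. Peaks of all marks were short, with a median width of 316 bp for H3K4me1, 244 bp for H3K4me3 and 238 bp for H3K27ac. The shortest peak was 200 bp in every list. Only 45 H3K4me3 peaks and 3 H3K27ac peaks reached 1 kb, against 984 H3K4me1 peaks. The lowest score, as given by the authors for each peak, was 10 in the H3K4me1 list and 20 in the other lists, so the lists did not share a lower limit.

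The second question was where the modifications occurred together. Of the H3K27ac peaks, 74.7% (74.0 to 75.5) shared at least 1 base with an H3K4me1 peak and 40.3% (39.4 to 41.2) with an H3K4me3 peak. The difference between these shares was 34.4 percentage points (33.0 to 35.8). Of the H3K4me1 peaks, 39.3% (38.5 to 40.1) met H3K27ac and 24.1% (23.4 to 24.8) met H3K4me3. Of the H3K4me3 peaks, 41.8% (40.1 to 43.4) met H3K4me1 and 37.6% (36.0 to 39.1) met H3K27ac. When the other list was rotated along each chromosome, the H3K27ac peaks met H3K4me1 in 2.52% of cases and H3K4me3 in 1.32%. The observed overlap lay 29.7-fold and 30.5-fold above these values. The overlap of H3K4me3 with H3K4me1 lay 16-fold above its rotated value of 2.61%. All 6 overlaps exceeded every one of 1000 rotations (two-sided permutation test, p = 0.001, the smallest value these rotations can give). Moving a list by only 20 to 200 kb, which leaves it in the same neighbourhood, gave 5.12% for H3K27ac with H3K4me1 and 3.28% for H3K4me3 with H3K4me1.

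Joined into 139902 non-overlapping regions, the peaks fell into 7 combinations. The enhancer-type combination of H3K27ac with H3K4me1 and without H3K4me3 was found at 23866 regions (17.1%). All marks were present at 15179 regions (10.8%), and H3K27ac with H3K4me3 but without H3K4me1 at 6366 regions (4.55%). H3K4me1 with H3K4me3 and without H3K27ac was found at 8748 regions (6.25%). H3K4me1 stood alone at 51479 regions (36.8%), H3K4me3 at 27095 (19.4%) and H3K27ac at 7169 (5.12%). Counted per list, 51.9% (51.2 to 52.6) of H3K4me1 peaks and 47.1% (45.3 to 49.1) of H3K4me3 peaks met no other mark, against 13.3% (12.9 to 13.8) of H3K27ac peaks. These shares depended on list length. When every list was shortened to its 53712 strongest peaks, a setting chosen after seeing the data, they were 36.5% (35.8 to 37.3) for H3K4me1, 53.0% (51.3 to 54.9) for H3K4me3 and 24.0% (23.4 to 24.6) for H3K27ac.

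**Figure D1:**
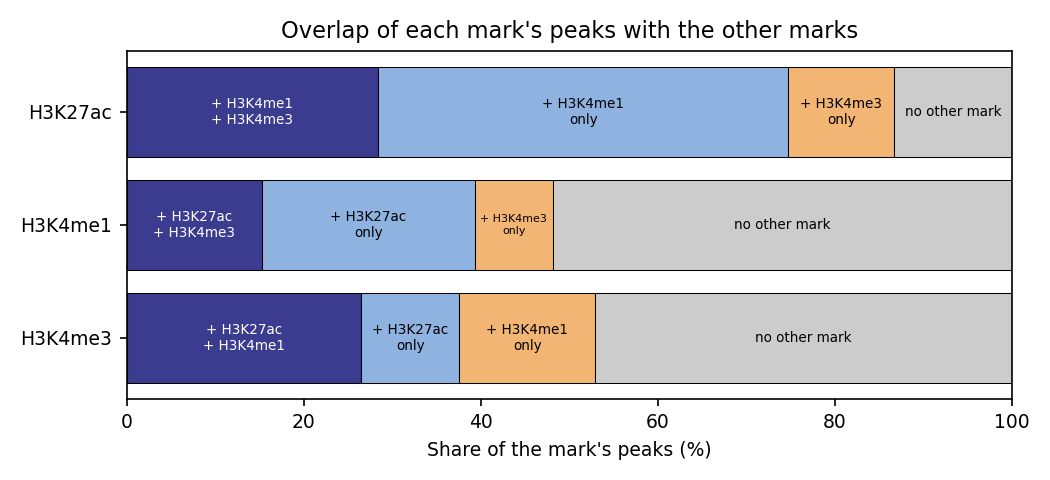
Share of the peaks of each mark (percent, horizontal axis) by which of the other marks' peaks they share at least 1 base with. H3K27ac peaks without another mark make up 13.3% of their list, and H3K4me1 and H3K4me3 peaks without another mark make up 51.9% and 47.1%.

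Peaks with higher scores more often carried another modification. From the weakest to the strongest decile of the H3K4me1 list by score, the share with H3K27ac rose from 8.07% (7.47 to 8.68) to 90.2% (89.5 to 90.9). From the weakest to the strongest decile of the H3K27ac list, the share with H3K4me1 rose from 56.7% (55.2 to 58.3) to 96.0% (95.4 to 96.6). The share of H3K27ac peaks with H3K4me3 stayed between 34.8% and 40.5% over deciles 1 to 9 and was 53.3% (51.3 to 55.2) in the strongest decile. For H3K4me3 peaks, the share with H3K27ac rose from 25.3% (23.8 to 26.8) to 68.9% (65.8 to 72.2), and the share with H3K4me1 rose from 31.1% (29.4 to 32.6) to 67.4% (64.1 to 71.1). Among the 575 strongest H3K4me3 peaks, the top 1% of the list, 99% (98.1 to 99.7) met H3K27ac and 79.0% (75.5 to 82.1) met H3K4me1. These peaks had a median width of 524 bp, and 200 rotations gave means of 1.81% and 3.62% for them. Across overlapping pairs of peaks, which are not independent replicates, scores of H3K27ac and H3K4me1 had a Spearman correlation of 0.585 (0.577 to 0.592). The correlation was 0.394 (0.381 to 0.408) for H3K27ac with H3K4me3 and 0.281 (0.268 to 0.293) for H3K4me1 with H3K4me3.

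**Figure D2:**
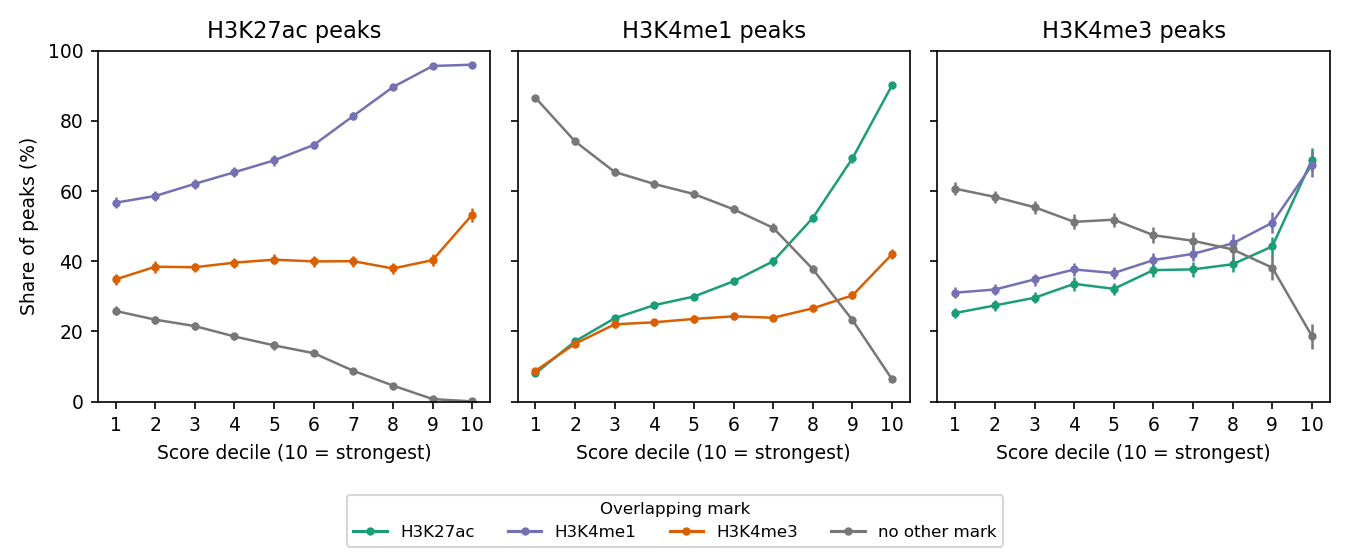
Share of H3K27ac, H3K4me1 and H3K4me3 peaks (percent, vertical axes) that overlap each other mark or none, by deciles of the score within the list, with 95% block bootstrap intervals. The share of H3K4me1 peaks with H3K27ac climbs from 8.07% in the weakest decile to 90.2% in the strongest.

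The arrangement of the marks around each other was examined next. Around the strongest 10% of H3K4me3 peaks, 65.0% of peak centres lay inside an H3K4me1 peak and 65.2% inside an H3K27ac peak. At 500 bp upstream in genome coordinates these shares were 4.58% and 1.86%, and at 1 kb they were 5.16% and 2.36%. Around all H3K27ac peaks, H3K4me1 covered 74.6% of the centres and 6.65% of positions 500 bp upstream. These shares count called peaks, and the level of a mark at the centre and beside it was not measured. In overlapping pairs of peaks the median distance between centres was 43 bp for H3K27ac with H3K4me1, with a 90th percentile of 149 bp. Pairs that overlapped after rotation of a list, which share the limit set by peak widths, had a median of 156 bp (95% range 148 to 164 over 200 rotations). The median was 24.5 bp for H3K27ac with H3K4me3, against 134 bp after rotation, and 24.5 bp for H3K4me1 with H3K4me3, against 159 bp.

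**Figure D3:**
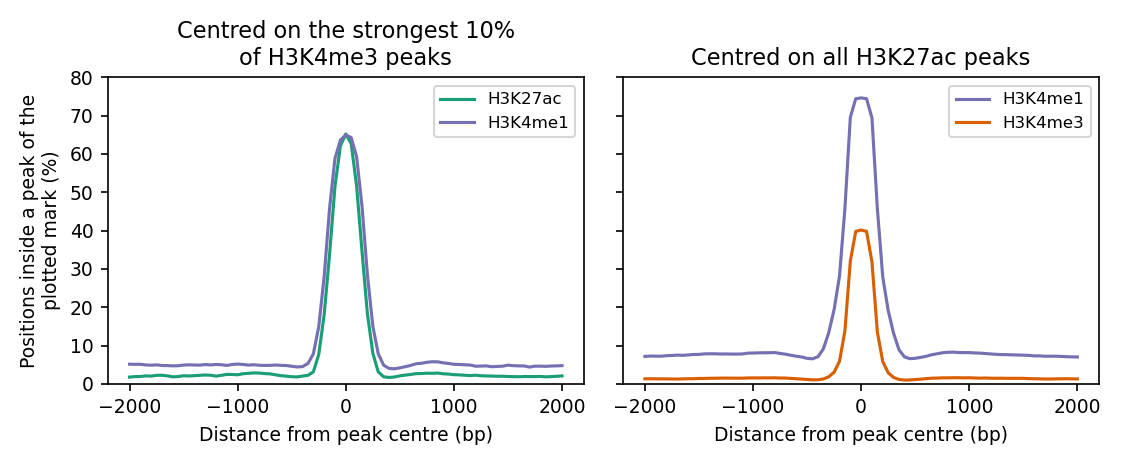
Percentage of positions inside a peak of the plotted mark (vertical axis) at distances of up to 2000 bp from the centres of the strongest 10% of H3K4me3 peaks (left) and of all H3K27ac peaks (right). Coverage by H3K4me1 is 65.0% at the centre of strong H3K4me3 peaks and 4.58% at 500 bp upstream.

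Candidate distal regulatory regions were taken as H3K27ac peaks that met H3K4me1 and lay over 2 kb from any H3K4me3 peak. Distance to H3K4me3 stood in for distance to annotated promoters, because no gene annotation of this build was used. There were 21686 such regions, 40.4% (39.4 to 41.4) of the H3K27ac list, with a median width of 245 bp. Their median distance to the nearest H3K4me3 peak was 15321 bp, with quartiles of 6891 and 33900 bp. How many H3K4me3 peaks lie at promoters was not tested, so these values are not distances to promoters. They were somewhat weaker than H3K27ac peaks with both other marks: 56.2% of them were in the stronger 50% of the list against 62.0%, a difference of -5.78 percentage points (-6.81 to -4.66). The 5 strongest lay on chromosome 2 (88651061 to 88651421, score 1201), chromosome 4 (46015283 to 46015754, score 1085), chromosome 15 (32715147 to 32715633, score 1082), chromosome 10 (19914404 to 19914756, score 1033) and chromosome 6 (146964065 to 146964516, score 1028). The region on chromosome 10 was 60333 bp from the nearest H3K4me3 peak and the region on chromosome 6 was 6247 bp away. The number of regions was 40149 when H3K4me3 was ignored and 13690 when only the stronger 50% of each list was used.

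H3K27ac peaks were clustered along the genome. Peaks joined across gaps of up to 10 kb formed 29007 regions, against a mean of 42800 (95% range 42644 to 42942 over 100 placements) for peaks placed at random on the same chromosomes. The random placement used the whole span of each chromosome and left out no sequence, so it is a lenient comparison. Of the gaps between neighbouring H3K27ac peaks, 10.8% were within 1 kb. Domains split into several short calls may therefore contribute. Most regions (67.8%) held 1 peak, and 450 held 10 or more. The 100 regions with the most H3K27ac-covered bases held 2329 peaks, 4.34% of the list, with a median length of 58.2 kb. All 100 held H3K4me1 peaks and 98 held at least 1 H3K4me3 peak. Their H3K27ac peaks met H3K4me1 more often than H3K27ac peaks elsewhere (92.3% against 74.0%, difference 18.4 points, 17.0 to 19.8) and H3K4me3 less often (20.3% against 41.2%, difference -20.9 points, -22.9 to -18.6). They were also stronger, with 71.0% in the stronger 50% of the list against 49.3% elsewhere. Ranking by covered bases favours wide peaks, and width and score of H3K27ac peaks had a Spearman correlation of 0.587. The choice of regions may therefore give part of this difference. With peaks elsewhere weighted to the same score deciles, a comparison chosen after seeing the data, the difference was 10.3 points (9.02 to 11.6) for H3K4me1 and -23.7 points (-25.8 to -21.2) for H3K4me3. The 100 regions held a median of 25 H3K4me1 peaks, and no rotated or shifted value was computed for them. How much of the higher overlap with H3K4me1 comes from the local density of peaks is therefore unknown. Weighting by score does not remove it. Chromosome 19 held 15 of the 100 regions and chromosome 10 held 13.

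The top-ranked cluster spanned 157 kb of chromosome 19 (53276170 to 53433524) and held 60 H3K27ac, 78 H3K4me1 and 17 H3K4me3 peaks. A cluster of 92.5 kb on chromosome 7 (139062229 to 139154757) held 48 H3K27ac, 48 H3K4me1 and 9 H3K4me3 peaks. The cluster on chromosome 4 (132271994 to 132380691) held 44 H3K27ac, 50 H3K4me1 and 8 H3K4me3 peaks. The next in rank lay on chromosome 20 (11511610 to 11604146), chromosome 10 (18861842 to 18984744), chromosome 19 (14690598 to 14776345), chromosome 16 (49290305 to 49368497), chromosome 11 (112922513 to 113014990), chromosome 19 (10813833 to 10864271) and chromosome 5 (4355630 to 4484734), with 32 to 42 H3K27ac peaks each. The order depended on how peaks were joined: only the clusters on chromosomes 7 and 4 stayed among the top 10 with joining distances of 5 and 20 kb and when ranked by score times width, whereas 9 of the 10, all but the one on chromosome 10, stayed among the top 100 in these settings.

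Wide H3K4me3 domains were examined because broad H3K4me3 is a known feature of genes that define cell identity. The cut used here was relative to the list, and no listed H3K4me3 peak was wider than 2097 bp. The domains below can therefore not be equated with that feature. Peaks joined across gaps of up to 1 kb formed 53853 domains, of which 94.0% were 1 peak. The widest 5%, 2694 domains of at least 892 bp, met H3K27ac in 56.1% of cases against 37.8% of the other domains, a difference of 18.3 points (15.2 to 21.3). For H3K4me1 the shares were 57.5% and 42.3%, a difference of 15.2 points (12.3 to 18). With rotated lists, which account for width but not for the number of joined peaks, the differences were 2.76 and 4.67 points. A domain of several peaks has more chances to meet another mark. For peaks as listed, without joining, the widest 5% differed by 25.5 points for H3K27ac and 15.0 points for H3K4me1. Wider H3K4me3 peaks also had higher scores (Spearman correlation 0.452), and domains were not matched on score. The 2 widest domains carried neither H3K27ac nor H3K4me1. They lay on chromosome 19 at 9151953 to 9156951 (4999 bp, 6 peaks) and at 57515561 to 57520267 (4707 bp, 5 peaks). Peaks covered 2127 and 1700 bp of them, and the rest was joined gaps. Both lay in bins of 1 Mb that were dense in H3K4me3 peaks without another mark, starting at 9000001 and 57000001, for which background stays open below. The third in width, on chromosome 4 at 159630904 to 159635598, contained an H3K4me3 peak with a score of 2035 and 1 peak of each other mark. The remaining domains of the 10 widest measured 3613 to 4635 bp. They lay on chromosome 7 (147731352 to 147735986) and chromosome 1 (158891353 to 158895554), both without other marks, and, with 1 to 5 peaks of each other mark, on chromosome 1 (99908626 to 99912707), chromosome 19 (57377495 to 57381454), chromosome 8 (133854648 to 133858561), chromosome 6 (92666620 to 92670328) and chromosome 1 (17739050 to 17742662). In the chromosome 7 domain, peaks covered 1389 of 4635 bp, and their highest score was 52 against a list median of 96.

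Peak density differed between chromosomes. Chromosome 19 held 54.2 H3K27ac, 90.3 H3K4me1 and 82.3 H3K4me3 peaks per Mb of the span covered by the lists. Relative to the other autosomes this was 2.88-fold (2.02 to 3.77), 2.59-fold (1.85 to 3.36) and 4.23-fold (3.36 to 5.13) higher. The X chromosome was sparse, at 0.338 (0.252 to 0.426), 0.408 (0.309 to 0.504) and 0.468 (0.336 to 0.635) times the autosomal density for H3K27ac, H3K4me1 and H3K4me3. The Y chromosome carried 63 H3K27ac, 165 H3K4me1 and 63 H3K4me3 peaks. These densities and counts were not adjusted for the number of X or Y copies in the tissue, so they do not measure modification per copy.

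**Figure D4:**
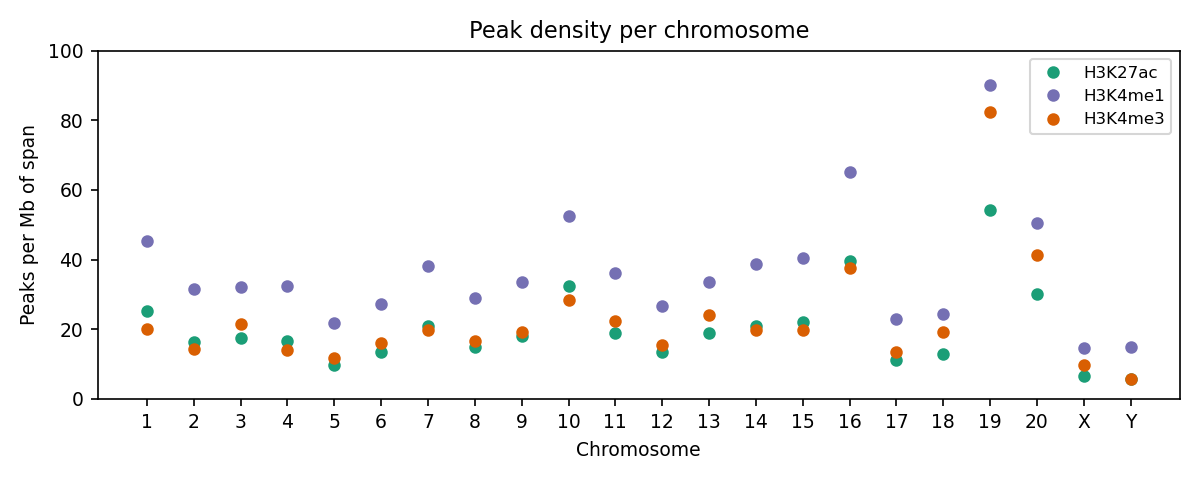
Peaks per Mb of span (vertical axis) on each chromosome for H3K27ac, H3K4me1 and H3K4me3, 1 point per mark. Chromosome 19 has the highest density of every mark, at 54.2, 90.3 and 82.3 peaks per Mb, and the X and Y chromosomes lie low.

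The modifications also differed in where along a chromosome they were dense. Over 2865 bins of 1 Mb, the numbers of H3K27ac and H3K4me1 peaks had a Spearman correlation of 0.949 (0.942 to 0.954). The correlation of H3K27ac with all H3K4me3 peaks was 0.649 (0.612 to 0.679). Bins are not independent replicates. The bin with the most H3K27ac peaks, at 17000001 to 18000000 on chromosome 19, held 159 H3K27ac and 84 H3K4me3 peaks, of which 13 met no other mark. The bin at 36000001 to 37000000 on the same chromosome, chosen after its values were seen, held 6 H3K27ac, 17 H3K4me1 and 238 H3K4me3 peaks, of which 224 met no other mark. The genome-wide medians were 11, 24 and 15 peaks per bin for H3K27ac, H3K4me1 and H3K4me3.

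**Figure D5:**
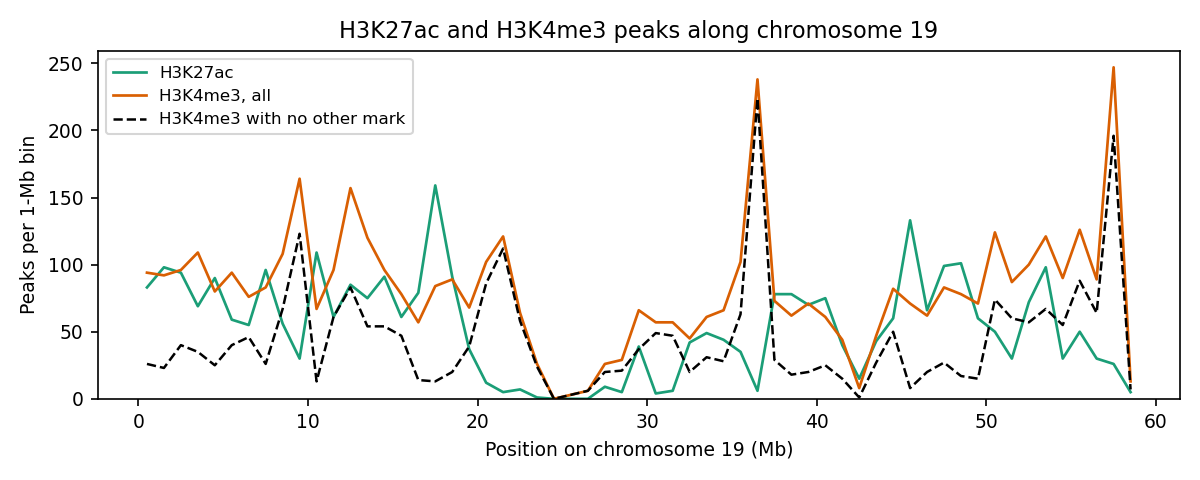
Number of peaks per 1-Mb bin (vertical axis) along chromosome 19 for H3K27ac, all H3K4me3 and H3K4me3 peaks that meet no other mark. H3K27ac is highest in the bin starting at 17000001 (159 peaks), and H3K4me3 peaks without another mark are highest in the bin starting at 36000001 (224 peaks).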

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

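The local shift, the common lowest score, the absence of a shared base with H3K4me3, lists of equal length, the weighting by score and the 10 bins left out were chosen after seeing the data. All 36 alternatives run on the 6 overlaps, with other overlap rules, stronger peaks, a common lowest score, a local shift or 10 bins left out, kept the overlap above its value for rotated or shifted lists (two-sided permutation tests). A reciprocal overlap of 50% lowered the share of H3K27ac peaks with H3K4me1 from 74.7% to 59.9%, and the stronger 50% of each list lowered the share with H3K4me3 from 40.3% to 30.8%. By construction, the stronger 50% of each list held 27002 H3K27ac, 49661 H3K4me1 and 29101 H3K4me3 peaks, where ties at the median score were kept. With every list shortened to the length of the shortest, the share without another mark was 36.5% for H3K4me1, 53.0% for H3K4me3 and 24.0% for H3K27ac. Merging peaks within 1 kb left 47936, 82157 and 53853 peaks. The number of candidate distal regions was 21686 at 2 kb from H3K4me3 and 17999 at 5 kb. It was 40149 when H3K4me3 was not considered and 13690 in the stronger 50% of each list. Joining H3K27ac peaks within 5 or 20 kb gave 35876 or 21513 regions in place of 29007. Of the top 10 regions, 4 overlapped the top 10 at 5 kb and 3 at 20 kb, and of the top 100, 57 and 66 did. Ranking by score times width kept 7 of the top 10 and 78 of the top 100. Wide H3K4me3 domains met H3K27ac more often than other domains by 18.3 to 25.5 points and H3K4me1 by 15 to 18.6 points under all settings run. No paired analysis was possible because each mark had 1 peak list for both of its libraries, so values carry no replicate number; for the same reason no replicate could be left out. The alternatives fixed beforehand for start sites, gene lists, repeats and motifs were not run, as no annotation or sequence of the same build was used. Without read totals, a site missing from a list cannot be called unmodified.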

Other observations

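All comparisons in this part were chosen after the lists had been examined. The tests of shared background, of placement within neighbourhoods and of list length were chosen after the values they measure had been seen, and the tests of the score in dense bins and of the strongest 1% of H3K4me3 peaks before.

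H3K4me3 peaks that met no other mark were unevenly spread. Within 5 Mb of a chromosome end they made up 55.1% (49.5 to 61.1) of H3K4me3 peaks, against 44.0% (41.9 to 46.3) over 20 Mb from both ends. The difference of 11.1 points (5.46 to 16.9) was 10.8 points (5.63 to 16.5) without the 10 densest bins described below. H3K4me1 and H3K27ac peaks went the other way: the share that met no other mark was lower near the ends, with a difference of -10.1 points (-11.6 to -8.5) for H3K4me1 and -4.92 points (-5.97 to -3.75) for H3K27ac. These shares depend on the density of the other lists and were not set against rotated lists. Near the ends lay 8745 H3K4me3, 5340 H3K27ac and 9130 H3K4me1 peaks. Over 20 Mb from both ends there were 31404, 32344 and 62381. H3K4me3 peaks were thus relatively more frequent near the ends, and the opposite directions are not independent results. On the X chromosome 66.7% of H3K4me3 peaks met no other mark, the highest share of any chromosome. On chromosome 1 36.8% did, the lowest. Of the X-linked H3K27ac peaks 79.6% met H3K4me1 and 30.1% met H3K4me3, and of the 63 on the Y chromosome 84.1% and 17.5% did. Without the 10 densest bins, the H3K4me3 density of chromosome 19 relative to the other autosomes was 3.86-fold in place of 4.23-fold.

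The 10 bins of 1 Mb with the most H3K4me3 peaks that met no other mark held 1386 of them, 5.12% of that class, and began at 36000001, 57000001, 9000001 and 21000001 on chromosome 19, at 48000001, 51000001 and 52000001 on chromosome 3, at 6000001 on chromosome 20, at 132000001 on chromosome 11 and at 176000001 on chromosome 6. Calls near the threshold are argued against: the median score of these peaks was at the 69.3 percentile of the H3K4me3 list (64.6 to 73.4), against 41.3 for the other H3K4me3 peaks without another mark. This interval and the others in this paragraph come from resampling the 10 bins, so they describe only the spread among them. Whether background raised all antibodies alike in these bins was not decided. The H3K4me1 median was 0.562 (0.208 to 1.71) of its genome median per bin, against 9.17 (8.07 to 13.4) for H3K4me3 and 1.23 (0.545 to 2.36) for H3K27ac. Choosing bins by H3K4me3 peaks without another mark favours few other peaks, so these ratios cannot settle it. In the 10 bins with the most H3K4me3 peaks of any kind, the medians were 2.04 (0.292 to 2.96) for H3K4me1, 2.36 (0.636 to 4.55) for H3K27ac and 9.97 (8.47 to 13.2) for H3K4me3. Those bins are no separate check, since 7 are the same and the other 3 held at least 50 H3K27ac and 71 H3K4me1 peaks. A stricter form of the test, set first, needed both other marks to stay under a fixed part of the H3K4me3 ratio there too. It left the question undecided (upper limit 4.55 for H3K27ac against a bound of 4.23). A form that 1 mark could meet was met by H3K4me1, but it was set after these values were seen. A background that acts unequally on the antibodies, sequence composition and copy number were not tested and stay open, and no biological explanation was tested.

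The overlap of H3K4me1 with the centres of H3K4me3 peaks is a pattern to look at again, because H3K4me1 is usually low where H3K4me3 is highest, although called peaks do not give its level. Independent placement within the same neighbourhoods is argued against, since moving 1 of the lists by 20 to 200 kb left 3.28% of H3K4me3 peaks with H3K4me1 against 41.8% observed. Signal that any antibody gives at open or well amplified sites may contribute: it predicts that the strongest H3K4me3 peaks meet H3K4me1 most, and 79.0% (75.5 to 82.1) of the strongest 1% did, against 38.5% in the middle quintile of the list. Strong sites being easier to call with every antibody would give the same result. A mixture of cell types in bulk tissue was not tested and stays open.

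More than 50% of H3K4me1 peaks met no other mark (51.9%, against 13.3% of H3K27ac peaks), and the H3K4me1 list was both longer and called down to a lower score. With every list shortened to its 53712 strongest peaks, which left H3K4me1 peaks with a score of at least 56, the shares were 36.5% (35.8 to 37.3) and 24.0% (23.4 to 24.6). The 12.5 points (11.9 to 13.1) that remained argue against the longer list and lower score as the whole cause of this difference. That it became smaller leaves them open as part of the cause. A bound set first, a share over 2 times that of H3K27ac, was not reached. H3K27ac and H3K4me1 peaks met each other in nearly equal numbers (40149 and 39039 in the full lists). In lists of equal length this overlap therefore nearly cancels. What remained mainly reflects overlap with H3K4me3 and cannot show why H3K4me1 peaks lack H3K27ac. A difference in the number of reads behind the lists stays open, as does H3K4me1 at enhancers that are not active, which was not tested.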
